A study of Mus musculus with 22 samples.

How the data were processed

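The deposited data were RNA sequencing counts from mouse stomach organoids, which are epithelial cultures grown in Matrigel. Per the labels, total RNA was taken with Trizol, and the libraries fell into 3 tables: normal gastric organoids with a scrambled guide or either of a pair of Ezh2 guides, tumor organoids with or without an Ezh2 guide, and tumor organoids with an Ezh2 guide that also carried a scrambled guide or either of a pair of Tfap2c guides. Per the submitters' processing notes, reads were aligned with STAR 2.6.0 to the mouse genome build mm10 and DESeq2 1.22.2 was used. The counting tool, the annotation, the strand setting and any filter were not given in the sources used here, so counts of antisense, overlapping and paralogous genes carry an uncertainty that could not be measured.

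The authors deposited raw counts per gene symbol for every library, as whole numbers with a different total in each library, and these counts were the input to every test. The authors also deposited a signal table for each count table, and these normalized values equalled the counts divided by 1 size factor per library, so they served only as a check. Each table held 24421 genes. The symbols of 27 genes had been turned into dates, and these genes were left unnamed. No column of these tables belonged to a sample outside the groups.

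Each table was fitted separately with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with the group factor and its minimum count of 10, libraries were scaled by TMM, and 1 mean per group was fitted with no block. Contrasts were tested with the quasi-likelihood F test, 2-sided, and p-values were adjusted over the genes tested by the Benjamini-Hochberg method at a threshold of 0.05. The standard error of a log2 fold change was its size over the square root of the F statistic. Counts of genes were also taken at an absolute log2 fold change of at least 1. The comparisons were each guide against the scrambled guide, the mean of both guides against it, the guides against each other, the tumor organoids with against those without the Ezh2 guide, and the difference of the Ezh2 guide effects between tumor and normal organoids in 1 joint fit. Levels are in CPM, the counts scaled to the library's total over the genes kept times its TMM factor, as mean and SD. Xist alone was scaled to the library total without that factor. The 3 tables were normalized separately, so levels are set side by side only within a table.

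A collection of 39 gene lists, made of cell type markers, pathways and gene families, was fixed in advance. Lists with at least 3 tested genes were tested against all other genes with camera of limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists of the comparison, and again with an estimated correlation. Member counts were taken from the adjustment over all genes and from the adjustment over the list alone. Overlaps of calls were tested with Fisher's exact test, 1-sided, among the genes tested in both tables. The agreement of a pair of guides was set beside 20 negative binomial simulations of unchanged groups sharing the same controls, because the guides share their scrambled libraries.

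The groups, comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule named the targeted genes Ezh2, Tfap2c, Pten and Trp53, a fixed panel of squamous and gastric genes, and up to 8 genes per direction and main comparison. Those were the largest changes past the threshold with a mean of at least 1 CPM, libraries that did not overlap between the groups and, with a pair of guides, a call the same way under each guide. It also named the 4 members with the smallest adjusted p in each list past its test and the 5 shared genes with the largest smaller change per overlap. Any other gene in the text was chosen after its values were seen. In the comparison of tumor organoids the edgeR test called 0 genes, so the rule was applied there to the calls of DESeq2 1.42.0, a choice made after the values were seen.

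Alternatives were DESeq2 with its own size factors, edgeR with DESeq2-type (RLE) size factors, no filter on low counts, the replicate number as a block, only the libraries compared (both guides as 1 group for the mean of the guides), an estimated correlation for the lists, and leaving out each library in turn. Leaving out the libraries that stand apart, an offset for a smooth trend on transcript length, and DESeq2 without each tumor library in turn were added after the data were seen. Transcript lengths and gene positions came from GENCODE M21 (GRCm38, the same assembly as mm10), in coordinates counted from 1. Where a group had no counts, a fold is a lower bound computed against 3 counts over the group. Such floors cover counting error only.

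The procedure was tested on simulated data with planted changes at the sizes and spreads of these tables. At the spread of the normal organoids, edgeR recovered 15% of genes planted at 2-fold and 79% of those at 4-fold, with 5 false calls of 99, and DESeq2 recovered 47% and 93%, with 39 false calls of 179. At that of the organoids with Tfap2c guides, edgeR recovered 60% and 92%, with 10 false calls of 162, and DESeq2 77% and 96%, with 51 false calls of 224. At that of the tumor organoids, edgeR recovered 0% and 14%, with 4 false calls of 18, and DESeq2 4% and 48%, with 53 false calls of 105.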

Results

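RNA was sequenced from mouse stomach organoids in 3 sets of libraries. Normal gastric organoids carried a scrambled guide RNA (sgScramble) or a guide against Ezh2 (sgEzh2_1 or sgEzh2_2), with 3 libraries each and 15026326 to 22321843 counts per library. Ezh2 encodes the catalytic subunit of the Polycomb repressive complex PRC2, which methylates histone H3 at lysine 27. Tumor organoids, derived from tumor tissue, were Trp53-/- per the labels and carried a Pten guide (TP) or Pten and Ezh2 guides (TPE), with 2 libraries each and 12864217 to 19031002 counts. Organoids of the TPE genotype also carried sgScramble or a guide against Tfap2c (sgTfap2c_1 or sgTfap2c_2), with 3 libraries each and 16014020 to 30815010 counts. Tfap2c encodes the transcription factor AP-2 gamma. The labels do not say that replicates were separate cultures, so the p-values measure a spread between libraries that may be technical.

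In normal organoids Ezh2 mRNA (chromosome 6, 47530139 to 47595341, minus strand, mm10) was 57.1 ± 8.36 CPM with sgScramble, 28.1 ± 3.5 with sgEzh2_1 and 42.2 ± 10.7 with sgEzh2_2 (mean ± SD, n = 3 each). The libraries were at 52.1, 52.4 and 66.8 CPM, at 26.8, 25.4 and 32.1, and at 33.4, 38.9 and 54.2. Neither change passed the edgeR test, with log2 fold changes of -1.02 ± 0.24 (SE, adjusted p = 0.158) for sgEzh2_1 and -0.44 ± 0.24 (adjusted p = 0.37) for sgEzh2_2. The mean of both guides was -0.73 ± 0.20 (adjusted p = 0.142), and DESeq2 placed it at an adjusted p of 0.0496. In the tumor table Ezh2 was at 48.7 and 130 CPM in TP and at 38.7 and 34.9 in TPE, a log2 fold change of -1.28 ± 0.52 (adjusted p = 0.449). A guide can disrupt a protein without lowering its mRNA, and no protein was measured.

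Tfap2c mRNA (chromosome 2, 172549593 to 172558622, plus strand) was not lowered past the test by either Tfap2c guide. It was 37.5 ± 2.24 CPM with sgScramble, 35.6 ± 1.72 with sgTfap2c_1 and 26.6 ± 3.65 with sgTfap2c_2 in TPE organoids (n = 3 each). The log2 fold changes were -0.07 (adjusted p = 0.74) and -0.49 (adjusted p = 0.0548), and the mean of both was -0.28 ± 0.11 (adjusted p = 0.136). Without sgTfap2c_2 replicate 1 that mean was -0.27 and passed (adjusted p = 0.018), in a fit that called 7051 genes against 1725 in the main fit. Ezh2 itself rose with the Tfap2c guides, from 12.5 ± 1.71 CPM to 25.6 ± 3.04 and 26.2 ± 4.41, a log2 fold change of 1.04 ± 0.16 (adjusted p = 0.00432). Trp53 also rose, by 0.60 ± 0.11 (adjusted p = 0.00971), a call lost without sgScramble replicate 1 (adjusted p = 0.0512) or 3 (adjusted p = 0.0543), while Pten was at 0.23 (adjusted p = 0.119). In the other tables Pten and Trp53 did not pass. Pten was 137 ± 6.8, 136 ± 4.51 and 175 ± 19.9 CPM with sgScramble, sgEzh2_1 and sgEzh2_2, and 127 ± 67.6 and 85.7 ± 0.368 in TP and TPE. Trp53 was 89.3 ± 7.91, 94.5 ± 5.08 and 69.3 ± 9.74 CPM in the normal groups and 76.3 ± 22.6 and 124 ± 94.8 in TP and TPE. In TPE with sgScramble, sgTfap2c_1 and sgTfap2c_2 it was 136 ± 4.27, 225 ± 18.9 and 188 ± 21.5 CPM, so Trp53 transcript was abundant in organoids labelled Trp53-/-, and gene-level counts do not show whether it is intact.

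**Figure D1:**
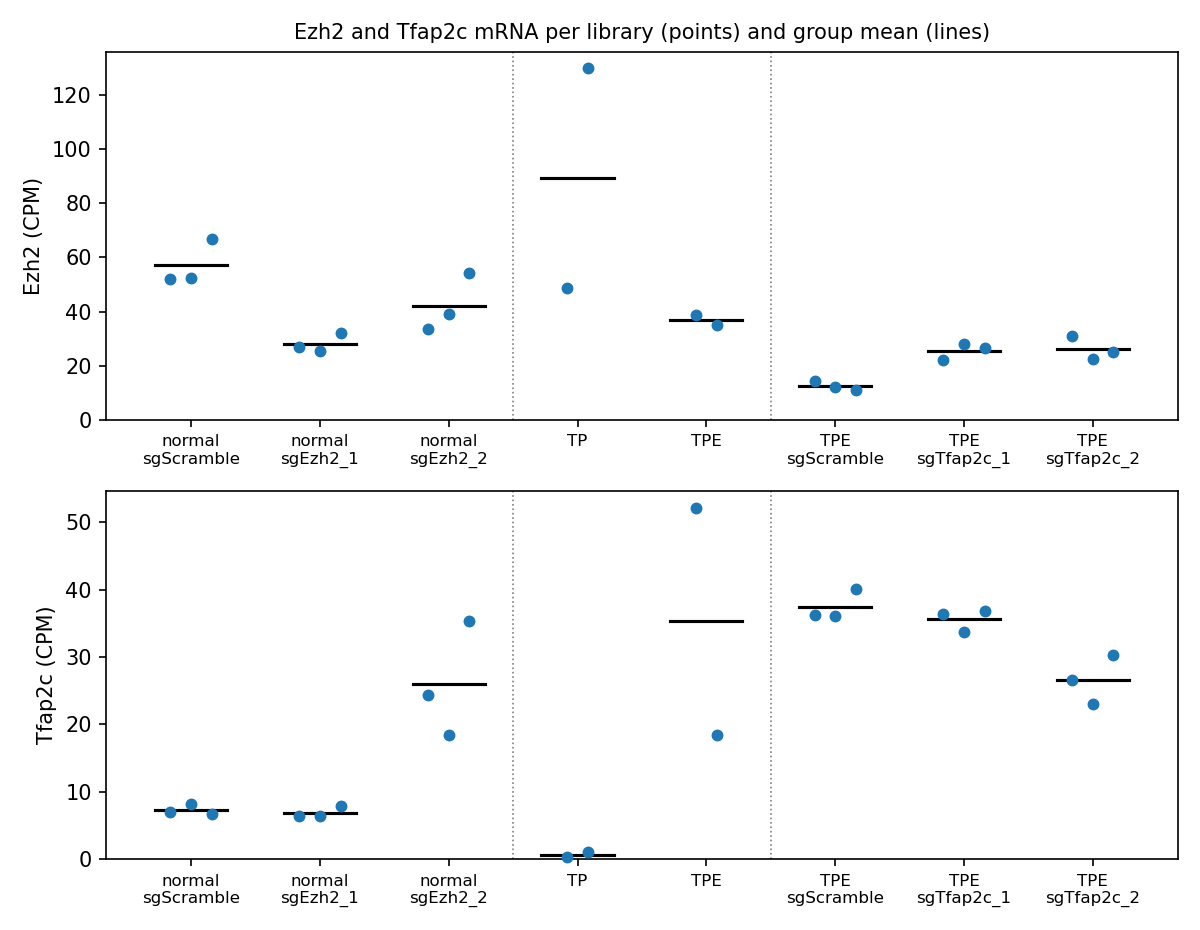
Ezh2 (top) and Tfap2c (bottom) mRNA in CPM in each library (points) with the mean of each group (lines). The dotted lines part the 3 tables, which were normalized separately. Tfap2c was 0.678 CPM on average in TP and 35.3 in TPE, and Ezh2 was 12.5 in TPE with sgScramble and above 20 in each library with a Tfap2c guide.

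The comparison of Ezh2 guides with sgScramble in normal organoids asks which transcripts change when PRC2 is targeted in untransformed gastric epithelium. A small group of genes changed with both guides. Higher were Car8, a carbonic anhydrase-related protein, from 10.5 ± 1.44 to 31.8 ± 6.78 CPM (2.99-fold, n = 3 and 6), and Pde3b, a cyclic nucleotide phosphodiesterase, from 1.94 ± 0.411 to 10.6 ± 2.93 CPM (5.41-fold). Zfpm2, a cofactor of GATA factors, rose from 0.116 ± 0.0789 to 2.05 ± 1.35 CPM (14.1-fold), and Twist1, a mesenchymal transcription factor, from 0.229 ± 0.149 to 2.02 ± 0.237 CPM (8.76-fold). Ckb, a brain-type creatine kinase also made by parietal cells, fell from 43.9 ± 16.7 to 10.5 ± 2.18 CPM (4.22-fold lower).

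These 5 genes passed the edgeR test with each guide and with their mean, at log2 fold changes of 1.58 ± 0.19 for Car8 (adjusted p = 0.0052), 2.44 ± 0.31 for Pde3b (adjusted p = 0.0056), 3.81 ± 0.53 for Zfpm2 (adjusted p = 0.00782), 3.13 ± 0.45 for Twist1 (adjusted p = 0.00928) and -2.08 ± 0.24 for Ckb (adjusted p = 0.00433). The rule also named Cyp2f2 (2.38, adjusted p = 0.0193), Mndal (3.13, adjusted p = 0.0225) and Gdpd2 (-1.39, adjusted p = 0.0113). Car8 lies on chromosome 4 (8143362 to 8239041), Pde3b on 7 (114415281 to 114539251), Zfpm2 on 15 (40655035 to 41104592), Twist1 on 12 (33957671 to 33959829) and Ckb on 12 (111669361 to 111672338). Leaving out any 1 library kept the calls of Car8, Pde3b, Zfpm2 and Ckb on the mean of both guides, while with sgEzh2_1 alone no gene kept its call through each of these fits. With the guide libraries as 1 group, all 34 named genes called on the mean lost their call, these included. With the replicate number as a block 25 of the 34 did. On the mean Twist1 missed the threshold without sgScramble replicate 1 (adjusted p = 0.072) or 2 (adjusted p = 0.0622). Mndal missed it without sgScramble replicate 1 (0.104) or 2 (0.11) and without any library of sgEzh2_1 (0.0533 to 0.0691). Gdpd2 missed it without sgScramble replicate 1 (0.0503) or 2 (0.0798) and sgEzh2_1 replicate 1 (0.057) or 3 (0.0559), and Cyp2f2 without any library of sgScramble or sgEzh2_1 (0.054 to 0.111).

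Across the 13020 genes tested, the mean of both guides called 193 genes, 49 higher and 144 lower, with 49 and 133 of them at least 2-fold changed, and 1547 genes at an unadjusted p under 0.05. DESeq2 called 222 higher and 357 lower. The edgeR count was 70, 59, 77, 72, 74 and 394 without sgScramble replicate 1 or 2, sgEzh2_1 replicate 1, 2 or 3, and sgEzh2_2 replicate 3. With the guide libraries taken as 1 group it was 0 (860 at an unadjusted p under 0.05).

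Columnar, neck and parietal markers were lower on the mean of both guides, and basal squamous, Hox and pit mucous cell genes were among the lists higher. Of 37 lists tested, 12 passed, 8 higher and 4 lower, and 2 held with an estimated correlation. Markers of gastric columnar identity fell (median log2 fold change -0.70, adjusted p = 9.99e-10, and adjusted p = 0.0445 with an estimated correlation), with 4 of 18 genes lower, 0 higher and 14 not past the test, and 7 lower adjusted over the list alone. The neck cell markers fell as well (median -0.23, adjusted p = 1.15e-05, and 0.0451 with an estimated correlation), with 2 of 5 genes lower over all genes and adjusted over the list alone. Parietal cell markers fell (median -0.92, adjusted p = 0.00195, but adjusted p = 0.129 with an estimated correlation), with 2 of 7 lower, and 3 lower and 1 higher adjusted over the list alone. Basal squamous markers rose (median 0.36, adjusted p = 1e-05, but adjusted p = 0.3 with an estimated correlation), with 2 of 26 genes higher, Dsc3 and Bnc1, and 3 adjusted over the list alone. Hox genes rose (median 0.30, adjusted p = 0.000189, but adjusted p = 0.3 with an estimated correlation), with 3 of 9 higher, Hoxc5, Hoxc6 and Hoxc8, and 4 adjusted over the list alone.

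The other 7 lists past the test lost their call with an estimated correlation. The unfolded protein and integrated stress list was higher (median 0.50, adjusted p = 2.6e-05, adjusted p = 0.3 with an estimated correlation), with 0 of 26 members called by edgeR, 4 by DESeq2 and 4 adjusted over the list alone. Cell cycle genes were higher (median 0.18, adjusted p = 2.65e-05, adjusted p = 0.599 with an estimated correlation), with 0 of 40 members called by edgeR, 7 by DESeq2 and 7 adjusted over the list alone. Pit mucous cell markers were higher (median 1.93, adjusted p = 0.0149, adjusted p = 0.599 with an estimated correlation), with 4 of 9 higher and 1 lower adjusted over the list alone. Developmental transcription factors outside Hox had 2 of 21 higher (5 higher and 1 lower adjusted over the list alone), with a median of 0.17 (adjusted p = 0.0136, adjusted p = 0.599 with an estimated correlation). The epithelial-mesenchymal transition list had 1 of 11 higher, Twist1 (3 adjusted over the list alone), with a median of 0.05 (adjusted p = 0.0493, adjusted p = 0.523 with an estimated correlation). NRF2 targets had a median of 0.25 (adjusted p = 0.041, adjusted p = 0.599 with an estimated correlation), with 2 of 26 higher and 1 lower adjusted over the list alone. Leukocyte markers had a median of -0.94 (adjusted p = 0.0458, adjusted p = 0.3 with an estimated correlation), with 1 of 6 higher and 2 lower adjusted over the list alone.

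Leaving out 1 library ended the call of several of these lists, here with the median without it. Developmental factors lost it without sgScramble replicate 1 (0.275), sgEzh2_1 replicate 1 (0.197), 2 (0.12) or 3 (0.177) and sgEzh2_2 replicate 1 (0.218) or 3 (-0.0841). The epithelial-mesenchymal list lost it without sgScramble replicate 1 (0.293) or 3 (-0.341), sgEzh2_1 replicate 3 (0.0123) and sgEzh2_2 replicate 1 (0.17) or 3 (-0.175). NRF2 targets lost it without sgScramble replicate 1 (0.189) or 2 (0.102), sgEzh2_1 replicate 2 (0.197) and sgEzh2_2 replicate 1 (0.216) or 2 (0.131). Leukocyte markers lost it without sgScramble replicate 3 (-0.382) and sgEzh2_2 replicate 1 (-0.857), 2 (-0.951) or 3 (-0.805), and pit markers without sgEzh2_2 replicate 1 (1.79) or 2 (1.67). The number of lists was 7 without sgEzh2_2 replicate 1. Among lists that did not pass, the median or mean differed in sign from the test for gastric stem cell, intestinal, Notch, MHC class I and ribosomal genes.

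The guides differed in gastric identity genes, which were lower with sgEzh2_2. Ezh2 mRNA had not passed the edgeR test with either guide. Whether the guide or a different founding cell pool lies behind these levels was not tested. Gata6 and Pdx1, transcription factors of the posterior foregut, were at 35.8 and 4.38 CPM with sgScramble and at 42.7 and 5.16 with sgEzh2_1. With sgEzh2_2 Gata6 was at 0.455 CPM and Pdx1 had 0 counts in each of its 3 libraries. Aqp5, a water channel of gastric neck and antral gland cells, was at 103, 102 and 1.04 CPM in the same order, and the simple-epithelium keratin Krt8 at 726, 624 and 129. The log2 fold changes with sgEzh2_1 and sgEzh2_2 were 0.25 and -6.22 for Gata6 (adjusted p of the difference = 0.000315), -0.01 and -6.63 for Aqp5 (8.57e-06) and -0.22 and -2.50 for Krt8 (0.00175). On the mean of both guides the call of Krt8 was lost without sgScramble replicate 1 or 2, any library of sgEzh2_1 or sgEzh2_2 replicate 1 (0.0711 to 0.106), while Gata6, Aqp5 and Pdx1 kept theirs. Columnar identity markers fell with sgEzh2_2 (median -1.18, adjusted p = 1.13e-12, and 0.02 with an estimated correlation), with 7 of 18 lower, and 12 lower and 1 higher adjusted over the list alone. The list differed directly between the guides (median 0.91, sgEzh2_1 over sgEzh2_2, adjusted p = 3.16e-10, and 0.0297 with an estimated correlation).

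Krt14, Krt6a, Dsc3, Hoxc6 and Tfap2c were higher with sgEzh2_2 and differed between the guides. Krt14, a basal keratin, was at 554, 830 and 3510 CPM with sgScramble, sgEzh2_1 and sgEzh2_2, Krt6a at 788, 784 and 3470, and the desmosomal cadherin Dsc3 at 42.2, 71.6 and 298. Hoxc6 (chromosome 15, 102998257 to 103011881) was at 9.65, 14.2 and 80.2 CPM, and Tfap2c at 7.26 ± 0.758, 6.85 ± 0.846 and 26 ± 8.51. Adjusted p-values of the direct difference were 0.0181 for Krt14, 0.00253 for Krt6a, 0.00246 for Dsc3, 0.00122 for Hoxc6 and 0.00259 for Tfap2c, which rose with sgEzh2_2 by 1.84 ± 0.28 (adjusted p = 0.00415). Basal squamous markers rose with sgEzh2_2 (median 0.72, adjusted p = 7.31e-07, but adjusted p = 0.263 with an estimated correlation), with 4 of 26 higher, and 11 adjusted over the list alone. Squamous differentiation genes had 7 of 37 higher and 2 lower (10 and 3 adjusted over the list alone) with a median of 0.52 (adjusted p = 0.0175, but adjusted p = 0.575 with an estimated correlation). Directly between the guides, sgEzh2_1 over sgEzh2_2, the basal squamous (median -0.65, adjusted p = 0.000708, 4 of 26 lower), squamous differentiation (-0.72, adjusted p = 0.000695, 1 of 37 higher and 11 lower) and Hox lists (-0.44, adjusted p = 0.00329, 3 of 9 lower) passed, but had adjusted p = 0.378 with an estimated correlation. Adjusted over the list alone 6 basal squamous genes were lower, 2 squamous differentiation genes higher and 14 lower, and 1 Hox gene higher and 3 lower. On the mean of both guides Krt14 (1.62, adjusted p = 0.0896), Krt6a (1.07, adjusted p = 0.103), Krt5 (0.57, adjusted p = 0.442), Trp63 (0.45, adjusted p = 0.437), Sox2 (-0.14, adjusted p = 0.841) and Tfap2a (0.02, adjusted p = 0.994) did not pass, and Ivl, a cornified envelope protein, fell (-1.31, adjusted p = 0.02). Ivl missed the threshold without sgScramble replicate 2 (0.105), any library of sgEzh2_1 (0.0721 to 0.0865) or sgEzh2_2 replicate 1 (0.0514). The calls of Hoxc5, Hoxc6 and Hoxc8 were lost without sgScramble replicate 1 (0.0559, 0.0711 and 0.0619) or 2 (0.0686, 0.094 and 0.0828), that of Dsc3 without sgScramble replicate 1 (0.0523) and that of Bnc1 without sgScramble replicate 1 (0.052) or 2 (0.0713).

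Of the gastric panel, Muc5ac (4.48, adjusted p = 0.174), Gkn2 (5.21, adjusted p = 0.191), Muc6 (-0.23, adjusted p = 0.971) and Tff2 (2.59, adjusted p = 0.447) did not pass on the mean of both guides. Gkn2, a pit cell gastrokine, rose with sgEzh2_2 to 15.5 CPM (adjusted p = 0.0256), from 0.0723 with sgScramble. Cdkn2a, a cell cycle inhibitor repressed by PRC2 in many cells, was lower with sgEzh2_2 (-2.61, adjusted p = 0.00964) and at -0.09 with sgEzh2_1. Tff1 had 0 counts and Cdx2 had 2 counts in the normal table.

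Interferon response genes moved in opposite directions with the guides. They rose with sgEzh2_1 (median 1.18, adjusted p = 5.77e-38, but adjusted p = 0.183 with an estimated correlation), with 2 of 43 higher and 28 adjusted over the list alone. With sgEzh2_2 they fell (median -1.12, adjusted p = 4.77e-09, but adjusted p = 0.575 with an estimated correlation), with 7 lower and 17 adjusted over the list alone. Between the guides 31 of the 43 genes differed, all higher with sgEzh2_1, and 38 were higher and 1 lower adjusted over the list alone (median 2.34, adjusted p = 3.85e-37, but adjusted p = 0.159 with an estimated correlation). Chosen after their values were seen, the antiviral genes Zbp1 (2.46 with sgEzh2_1, -1.32 with sgEzh2_2) and Rsad2 (2.10, -1.73) had adjusted p-values of the difference of 0.00811 and 0.0109. The unfolded protein and integrated stress list rose with sgEzh2_1 (median 0.59, adjusted p = 1.45e-16, but adjusted p = 0.183 with an estimated correlation), with 4 of 26 higher and 10 adjusted over the list alone.

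**Figure D2:**
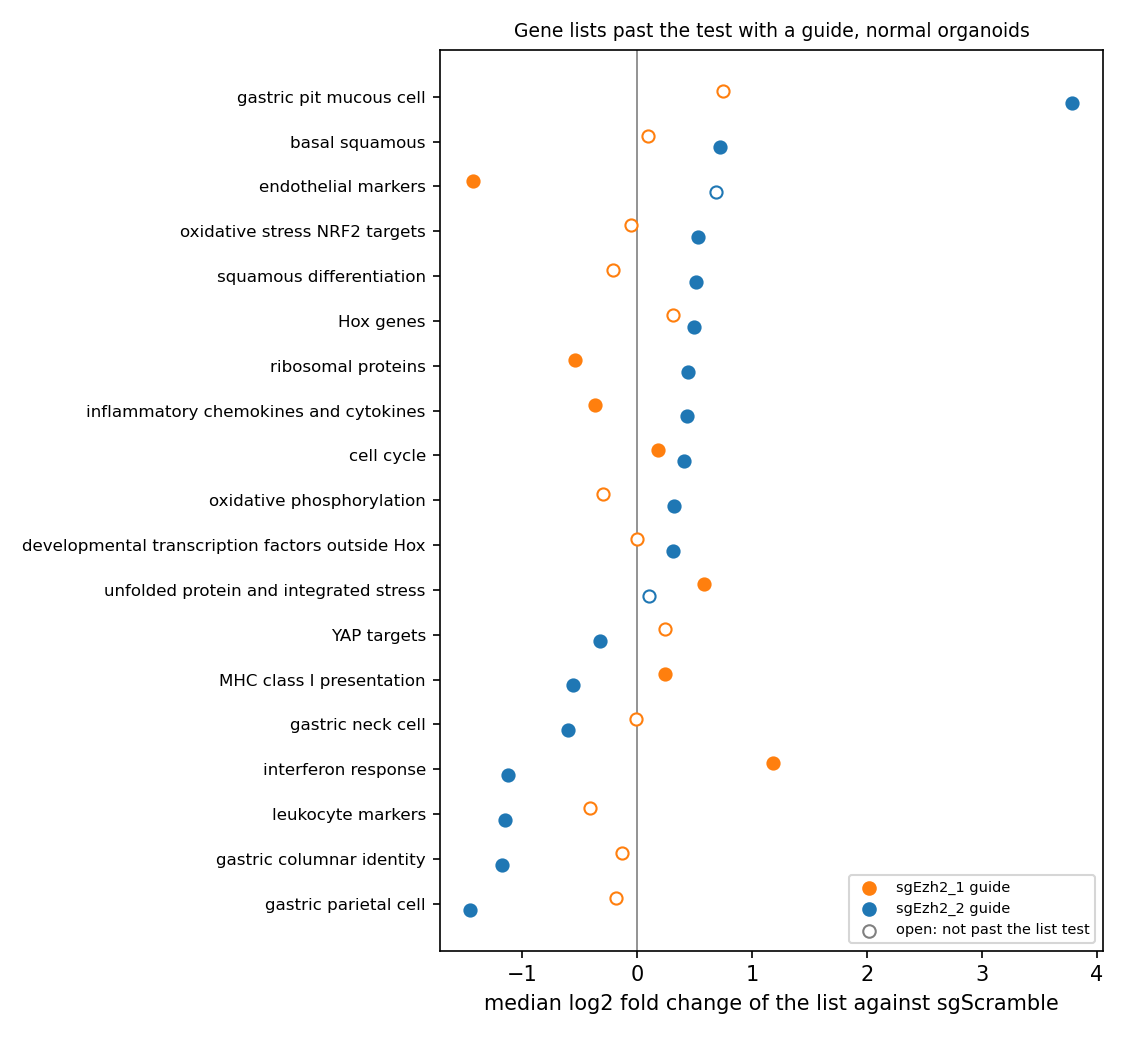
Median log2 fold change against sgScramble of each gene list past the test with at least 1 Ezh2 guide in normal organoids (orange sgEzh2_1, blue sgEzh2_2, open symbols not past the test). Interferon response genes were at 1.18 with sgEzh2_1 and -1.12 with sgEzh2_2, and columnar identity markers passed with sgEzh2_2 alone. Most of these calls were lost with an estimated correlation, which kept 0 lists with sgEzh2_1 and 2 with sgEzh2_2.

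Taken separately, sgEzh2_1 called 24 genes higher and 7 lower (1191 at an unadjusted p under 0.05, and 154 higher and 143 lower by DESeq2), and sgEzh2_2 called 261 higher and 416 lower. The direct comparison called 982 genes, 600 higher with sgEzh2_1 and 382 lower. Both guides called 6 genes higher, 2 lower and 3 in opposite directions. The opposite genes were Hp, an acute-phase protein (2.95 and -2.30), Nlrc5, an activator of MHC class I (2.08 and -1.68), and Stc2, a secreted stress hormone (1.79 and -2.36). Across genes, which are not independent replicates, the fold changes of the guides had r = 0.103, below the 0.491 that sharing controls gave in simulations of unchanged groups (highest 0.513). The count of sgEzh2_1 was 10 without sgScramble replicate 3. It was 0 by edgeR without sgScramble replicate 1 or 2 (1190 and 1047 at an unadjusted p under 0.05) and without sgEzh2_1 replicate 1, 2 or 3 (715, 753 and 694), where DESeq2 was not run. The count of sgEzh2_2 was 344, 312, 382 and 1461 without sgScramble replicate 1 or 2 and sgEzh2_2 replicate 1 or 3. That between the guides was 440, 468, 427, 572 and 1885 without sgEzh2_1 replicate 1, 2 or 3 and sgEzh2_2 replicate 1 or 3, and r was 0.202, 0.186 and 0.253 without sgScramble replicate 1, 2 or 3.

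A pair of the normal libraries, sgScramble replicate 3 and sgEzh2_2 replicate 2, stood apart from the rest of their groups, with a mean log2 difference of ribosomal protein genes from the table of 0.928 and 1.17 and TMM factors of 0.848 and 0.787. The ribosomal list fell with sgEzh2_1 (median -0.54, adjusted p = 0.000973, but adjusted p = 0.845 with an estimated correlation) and rose with sgEzh2_2 (0.44, adjusted p = 0.0027, but adjusted p = 0.8 with an estimated correlation), with 0 of 56 members called by edgeR or DESeq2 or over the list alone with either guide. Without both libraries, the mean of both guides called 675 genes, sgEzh2_1 310, sgEzh2_2 1788 and the direct comparison 2564.

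The comparison of TPE with TP organoids asks what distinguishes tumor organoids that also carry the Ezh2 guide. With 2 libraries per group edgeR called 0 of 13092 genes (1442 at an unadjusted p under 0.05, smallest adjusted p = 0.0962), and DESeq2 called 397 higher and 172 lower. In the simulated tumor data 53 of 105 DESeq2 calls were false, so a single DESeq2 call is weak evidence. With no filter on low counts, a setting planned as an alternative, edgeR called 326 genes, 54 of the 90 genes named for this comparison among them. The genes below are DESeq2 calls, and those from Hoxa2 to Ptgs2 also passed that unfiltered edgeR test (0.000125 to 0.00659). That fit uses the same libraries and was not simulated, so its share of false calls is unknown and it is no independent support. With RLE size factors or the replicate number as a block edgeR called 0 genes. Genes of the Hoxa cluster, which patterns the body axis, were higher in TPE. Hoxa2, Hoxa9 and Hoxa10 had 0 counts in TP and were at least 53.7-fold, 446-fold and 252-fold higher in TPE, at 5.16 ± 0.722, 42.9 ± 48 and 24.2 ± 27.4 CPM (n = 2 each). Hoxa5 was at 10.1 ± 2.04 CPM from 3 counts in TP and Hoxa3 at 15.5 ± 5.93 CPM from 1 count. Tfap2c was at 0.678 ± 0.53 CPM in TP and 35.3 ± 23.8 in TPE (log2 fold change 5.66 ± 0.80, DESeq2 adjusted p = 1.03e-09, edgeR adjusted p = 0.228).

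Other genes called by DESeq2 came from several functions. Fibroblast markers were higher as a list (median 2.54, adjusted p = 0.00536, but adjusted p = 0.46 with an estimated correlation, 0 of 7 by edgeR and 2 adjusted over the list alone), and the epithelial-mesenchymal transition list did not pass (0.75, adjusted p = 0.0661, adjusted p = 0.72 with an estimated correlation, 0 of 13 by edgeR, and 2 higher and 1 lower adjusted over the list alone). Twist2, a mesenchymal transcription factor, was at 19.3 ± 6.34 CPM in TPE and 0.131 ± 0.0288 in TP (adjusted p = 3.12e-11), and the collagen chaperone Serpinh1 at 45.8 ± 32.8 and 0.0758 ± 0.107 (2 counts in TP, adjusted p = 3.09e-11). Ror2, a Wnt5a receptor, was at 20 ± 12.7 CPM and at least 208-fold higher, and Eln, which encodes elastin, at least 244-fold. Col4a1, a basement membrane collagen, was 12-fold higher (3.59 ± 0.48, adjusted p = 1.05e-10) and Car9, a hypoxia-induced carbonic anhydrase, 9.6-fold (3.26 ± 0.58, adjusted p = 4.38e-06). Lower in TPE were the neutrophil chemokine Cxcl1 (5.57-fold, -2.48 ± 0.45, adjusted p = 5.86e-06), the pantetheinase Vnn1 (5.64-fold, -2.50 ± 0.37, adjusted p = 9.81e-09) and the prostaglandin synthase Ptgs2 (11.5-fold, -3.53 ± 0.76, adjusted p = 0.000348). These genes, from Hoxa2 to Ptgs2, kept their DESeq2 call without each library in turn. Sparc (4.80, adjusted p = 7.08e-08) lost it without TPE replicate 1 (0.0579), as did Lef1 (6.45, adjusted p = 1.07e-05, 0.111) and H2-Ab1 (3.29, adjusted p = 5.89e-06, 0.0569). Gkn2 was at least 1130-fold lower, from 2562 counts in TP replicate 1 alone, with 0 in TP replicate 2 and in TPE.

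**Figure D3:**
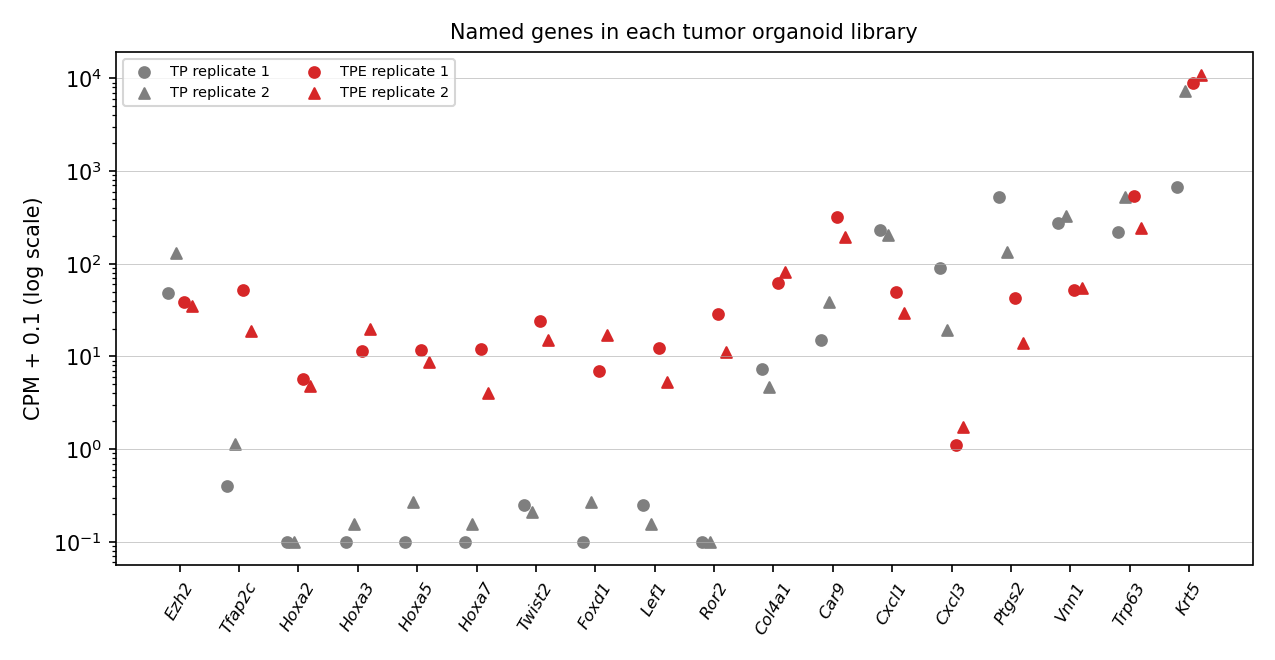
CPM plus 0.1 on a log scale of named genes in each tumor organoid library (grey TP, red TPE, circles replicate 1, triangles replicate 2). Tfap2c and the Hoxa genes were higher in both TPE libraries than in both TP libraries, while Krt5 was at 675 CPM in TP replicate 1, 7340 in TP replicate 2 and 8970 and 10900 in TPE.

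The squamous panel did not differ past either test between TPE and TP. Trp63, the basal squamous master regulator, was at 394 ± 211 and 374 ± 217 CPM (log2 fold change 0.08, edgeR adjusted p = 0.974), Krt5 at 1.31 (adjusted p = 0.682), Krt14 at 1.34 (0.487), Krt6a at 0.45 (0.764), Sox2 at -1.05 (0.366), Ivl at -1.96 (0.39) and Tfap2a at 0.19 (0.863). Cdkn2a was at 0.67 (0.586), Cdx2 at 1.75 (0.442), Tff2 at -3.55 (0.44) and Muc6 at -0.66 (0.852). Muc5ac was called lower by DESeq2 alone (-4.77, adjusted p = 0.0269), a call lost without TP replicate 1 (0.603, adjusted p = 0.999) or TPE replicate 2 (-4.05, 0.195). The TP libraries differed from each other in gastric genes, with Gkn2 at 194 and 0 CPM, Muc5ac at 36.8 and 0.444 and Krt20 at 528 and 2.72 in replicates 1 and 2. Across genes TP replicate 2 had r = 0.858 with TP replicate 1, and 0.87 and 0.854 with TPE replicates 1 and 2. TP replicate 1 had r = 0.797 and 0.804 with TPE. With 2 libraries per group, differences between single cultures cannot be told apart from an effect of the Ezh2 guide.

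Of 36 lists tested between TPE and TP, 16 passed, 12 higher and 4 lower, and 0 held with an estimated correlation by camera, each of them with 0 members called by edgeR. Hox genes were higher (median log2 fold change 7.18, or 5.55 with 5 genes absent from a group at their bound, adjusted p = 1.44e-18, but adjusted p = 0.46 with an estimated correlation), with 10 of 14 higher adjusted over the list alone and by DESeq2. Developmental transcription factors outside Hox, such as Foxd1, Zic2 and Foxf2, were higher (median 1.31, adjusted p = 1.04e-09, but adjusted p = 0.46 with an estimated correlation), with 12 of 43 higher adjusted over the list alone and 10 by DESeq2. The TFAP2 family was higher (median 2.87, adjusted p = 0.00352, but adjusted p = 0.46 with an estimated correlation), with 1 of 3 higher adjusted over the list alone, Tfap2c. Inflammatory chemokines and cytokines were lower (median -1.21, adjusted p = 1.13e-06, but adjusted p = 0.635 with an estimated correlation), with 7 of 27 lower adjusted over the list alone and 8 lower and 1 higher by DESeq2, among them Cxcl3 (-5.37, adjusted p = 6.94e-09) and Cxcl2 (-3.57, adjusted p = 0.00177, lost without TP replicate 1, 0.555). Cholesterol synthesis genes were lower (median -0.89, adjusted p = 1.37e-06, but adjusted p = 0.46 with an estimated correlation), with 0 of 24 adjusted over the list alone and 3 by DESeq2, the enzymes Idi1, Cyp51 and Fdps. These 5 lists kept their call without each library in turn. The DESeq2 calls of Cyp51 and Fdps were lost without any 1 library (0.0786 to 0.697) and that of Idi1 without TP replicate 1 (0.281) or TPE replicate 1 (0.436) or 2 (0.443), and Foxf2 missed without TPE replicate 1 (0.0554) or 2 (0.49) and Zic2 without TPE replicate 1 (0.195).

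The other 11 lists lost their call without 1 library. Higher in TPE were hypoxia and glycolysis (median 0.89, adjusted p = 4.6e-06, adjusted p = 0.731 with an estimated correlation, 1 of 30 higher adjusted over the list alone), MHC class I (0.79, 0.00208, adjusted p = 0.72 with an estimated correlation, 0 of 13 by edgeR, DESeq2 or over the list alone), Wnt targets (0.95, 0.00282, adjusted p = 0.629 with an estimated correlation, 2 of 17) and YAP targets (0.64, 0.00397, adjusted p = 0.72 with an estimated correlation, 2 of 20). MHC class II (2.09, 1 of 4), fibroblast markers (2.54, 2 of 7) and ribosomal proteins (0.35, 0 of 56 by edgeR, DESeq2 or over the list alone) each had an adjusted p of 0.00536, and 0.46, 0.46 and 0.822 with an estimated correlation. Basal squamous markers (0.52, 0.0148, adjusted p = 0.46 with an estimated correlation, 0 of 26 by edgeR, DESeq2 or over the list alone) and the Notch pathway (0.49, 0.0418, adjusted p = 0.72 with an estimated correlation, 1 of 14) were also higher. Leukocyte markers (-0.55, 0.0171, adjusted p = 0.72 with an estimated correlation, 2 of 5 lower) and interferon response genes (-0.71, 0.0176, adjusted p = 0.845 with an estimated correlation, 0 of 43 by edgeR, DESeq2 or over the list alone) were lower. Without TP replicate 1 the calls ended for basal squamous (median 0.442), Wnt (0.595), Notch (0.443), YAP (0.38), MHC class I (0.465), hypoxia (0.397), ribosomal (0.0865) and leukocyte genes (0.0975). Without TP replicate 2 they ended for MHC class II (1.58) and fibroblast markers (2.43), and the interferon list turned to a higher median of 0.719. Without TPE replicate 1 they ended for Wnt (0.343), Notch (0.486) and hypoxia genes (0.181), and without TPE replicate 2 for ribosomal genes (0.168). The mean log2 difference of interferon genes from the table was -0.963 and 1.32 in TP replicates 1 and 2. Of lists that did not pass, the median or mean differed in sign from the test for squamous differentiation, gastric stem cell, PRC2, p53, immediate early, endothelial and smooth muscle genes.

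Without TP replicate 2 edgeR called 101 genes between TPE and TP. Without TP replicate 1 or TPE replicate 1 or 2 it called 0 (1352, 915 and 742 at an unadjusted p under 0.05), where DESeq2 called 456, 275 and 254, and without TP replicate 2 DESeq2 called 1024. In fits with 1 library left in a group, that library is assumed to vary like the other group.

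The comparison of Tfap2c guides with sgScramble in TPE organoids asks which transcripts depend on this factor, whose mRNA was higher in TPE than in TP by DESeq2. Immediate early genes rose as a list. Inflammatory and interferon lists fell, but lost their call with an estimated correlation (adjusted p = 0.0947 and 0.655), and interferon genes were highest in sgScramble replicate 1 (at a mean log2 difference from the table of 1.46, against 0.115 and 0.413 in replicates 2 and 3). Lcn2, a siderophore-binding antimicrobial protein, fell from 102 ± 24.9 to 16.6 ± 3.63 CPM (6.15-fold lower, n = 3 and 6), and Steap4, a metalloreductase induced by inflammation, from 108 ± 9.38 to 17.9 ± 3.47 (6.06-fold lower). Cxcl1 fell from 273 ± 7.88 to 129 ± 11.6 CPM, and the Wnt antagonist and target Wif1 was 14-fold lower. Fos, a subunit of AP-1, rose from 195 ± 43.5 to 684 ± 41 CPM (3.5-fold), Adm, a vasodilator peptide induced by hypoxia, from 15 ± 3.37 to 89.1 ± 35.4 (5.61-fold), and Id3, an inhibitor of bHLH factors, from 18 ± 5.71 to 217 ± 133 (11.2-fold).

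Each of these genes passed with each guide. Log2 fold changes of the mean of both guides were -2.60 ± 0.11 for Steap4 (chromosome 5, 7960457 to 7982213, adjusted p = 2.25e-05), -2.62 ± 0.19 for Lcn2 (chromosome 2, 32384633 to 32388252, adjusted p = 0.000407), -3.80 ± 0.31 for Wif1 (adjusted p = 0.000562), 1.81 ± 0.15 for Fos (chromosome 12, 85473890 to 85477273, adjusted p = 0.000562), 2.49 ± 0.18 for Adm (adjusted p = 0.000407) and 3.48 ± 0.37 for Id3 (adjusted p = 0.00119). Other large rises were Sostdc1, a BMP and Wnt antagonist (8.75-fold, adjusted p = 0.000329), Edn2 (2.93, adjusted p = 0.000731) and Bpifb4, which had 0 counts with sgScramble and was at least 46.8-fold higher. Other large falls were Col14a1, a fibril-associated collagen (27.2-fold lower, adjusted p = 0.000562), the leukocyte activation antigen Cd69 (-4.69), Dcn (-4.73), Vnn3 (-3.95) and Irg1 (-3.74).

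edgeR called 1725 of 13485 genes, 936 higher and 789 lower, of which 386 and 255 changed at least 2-fold, with 3687 at an unadjusted p under 0.05 and 1442 higher and 1138 lower by DESeq2. The count was 719, 757, 525, 972, 948, 990 and 7051 without sgScramble replicate 1, 2 or 3, sgTfap2c_1 replicate 1, 2 or 3, and sgTfap2c_2 replicate 1. The last library stood apart from its group, with a TMM factor of 0.845 and a mean log2 difference of ribosomal protein genes of 0.931. With the guide libraries as 1 group the count was 1101.

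Of 36 lists tested with the Tfap2c guides 6 passed, 2 higher and 4 lower, and the immediate early list held with an estimated correlation. Immediate early genes rose (median 0.69, adjusted p = 5.03e-13, and 0.0369 with an estimated correlation), with 10 of 18 higher and 8 not past the test, and 12 higher and 1 lower adjusted over the list alone. Among them were Fos, Fosb (2.25, adjusted p = 0.000903), Egr1 (1.28, adjusted p = 0.000925) and Dusp1 (1.45, adjusted p = 0.000551), a phosphatase that turns off MAP kinases. Hypoxia and glycolysis genes rose (median 0.36, adjusted p = 8.52e-09, but adjusted p = 0.248 with an estimated correlation), with 11 of 31 higher, and 16 adjusted over the list alone. Examples were Adm, the angiogenic factor Vegfa (from 361 ± 0.782 to 721 ± 186 CPM, adjusted p = 0.00345), Car9 (0.96, adjusted p = 0.00147) and P4ha2 (0.71, adjusted p = 0.00365), the last lost with the guide libraries as 1 group (0.0864).

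Inflammatory chemokines and cytokines fell (median -0.94, adjusted p = 2.13e-22, but adjusted p = 0.0947 with an estimated correlation), with 16 of 28 lower and 12 not past the test, and 20 lower adjusted over the list alone. Examples beside Lcn2 were Ccl5, a T cell chemokine (-2.14, adjusted p = 0.000306), the granulocyte growth factor Csf3 (-1.33, adjusted p = 6e-04) and Cxcl1 (-1.09, adjusted p = 0.000769). Interferon response genes fell (median -0.95, adjusted p = 2.72e-11, but adjusted p = 0.655 with an estimated correlation), with 16 of 43 lower, and 27 adjusted over the list alone, among them Ifit1 (-2.37, adjusted p = 0.00874), Gbp2 (-2.13, adjusted p = 0.00777) and Zbp1 (-2.59, adjusted p = 0.000903). Wnt targets fell (median -0.34, adjusted p = 8.29e-05, but adjusted p = 0.528 with an estimated correlation), with 6 of 18 lower, and 7 lower and 1 higher adjusted over the list alone. They included Wif1, Lef1 (-1.08, adjusted p = 0.00406), Tnfrsf19 (-1.05, adjusted p = 0.00331) and Myc (-0.52, adjusted p = 0.0141). The calls of Lef1 and Tnfrsf19 were lost with the guide libraries as 1 group (0.106 and 0.15), and that of Myc without sgScramble replicate 2 (0.0649) or 3 (0.0788). Ribosomal protein genes fell (median -0.47, adjusted p = 1.73e-06, but adjusted p = 0.712 with an estimated correlation), with 3 of 56 lower, Rpl10 (0.0363), Rps11 (0.0181) and Rpl15 (0.05), and 0 adjusted over the list alone against 4 lower by DESeq2. Each of these 3 calls was lost without sgScramble replicate 1, 2 or 3 or sgTfap2c_1 replicate 1 or 2 (0.0514 to 0.191), with Rpl10 and Rpl15 also lost without sgTfap2c_1 replicate 3 (0.0801 and 0.103) or sgTfap2c_2 replicate 2 (0.0659 and 0.092) and Rpl15 without sgTfap2c_2 replicate 3 (0.0625). All 6 lists kept their call without each library in turn. Splits of the libraries, the real one included, gave as small a list p in 1 of 100 for immediate early and 2 for inflammatory genes. They did so in 10 for hypoxia, 18 for Wnt, 33 for interferon and 63 for ribosomal genes, so chance is not excluded for these 4 lists. A share of 1 of 100 is the smallest these splits can give, and the shares were not adjusted over the 36 lists tested. Chance is thus not excluded for the immediate early and inflammatory lists either.

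The genes of the squamous panel did not pass the edgeR test with the Tfap2c guides. Trp63 was at -0.25 (adjusted p = 0.18), Krt14 at -0.01 (0.983), Krt6a at -0.28 (0.197), Sox2 at -0.24 (0.156), Ivl at -0.37 (0.0783) and Tfap2a at 0.18 (0.536). Krt5 was at -0.39 (adjusted p = 0.0957) and passed by DESeq2 (8.14e-06). Without sgTfap2c_2 replicate 1 Trp63 (-0.197, 0.0113), Krt5 (-0.357, 0.000233), Krt6a (-0.212, 0.00687), Sox2 (-0.233, 0.0138), Ivl (-0.423, 0.00102) and Tfap2a (0.276, 0.0084) passed, and Cdkn2a turned from 0.14 (0.852) to -0.229 (0.0217). That fit called 7051 genes, against 1725 in the main fit, so passing there is not particular to the squamous panel. In the main fit Muc6 was at 1.16 (0.266). The basal squamous list had 1 of 26 genes higher and 3 lower (median -0.13, adjusted p = 0.375). Of lists that did not pass, the median or mean differed in sign from the test for pit, neck, enteroendocrine, leukocyte and smooth muscle genes.

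**Figure D4:**
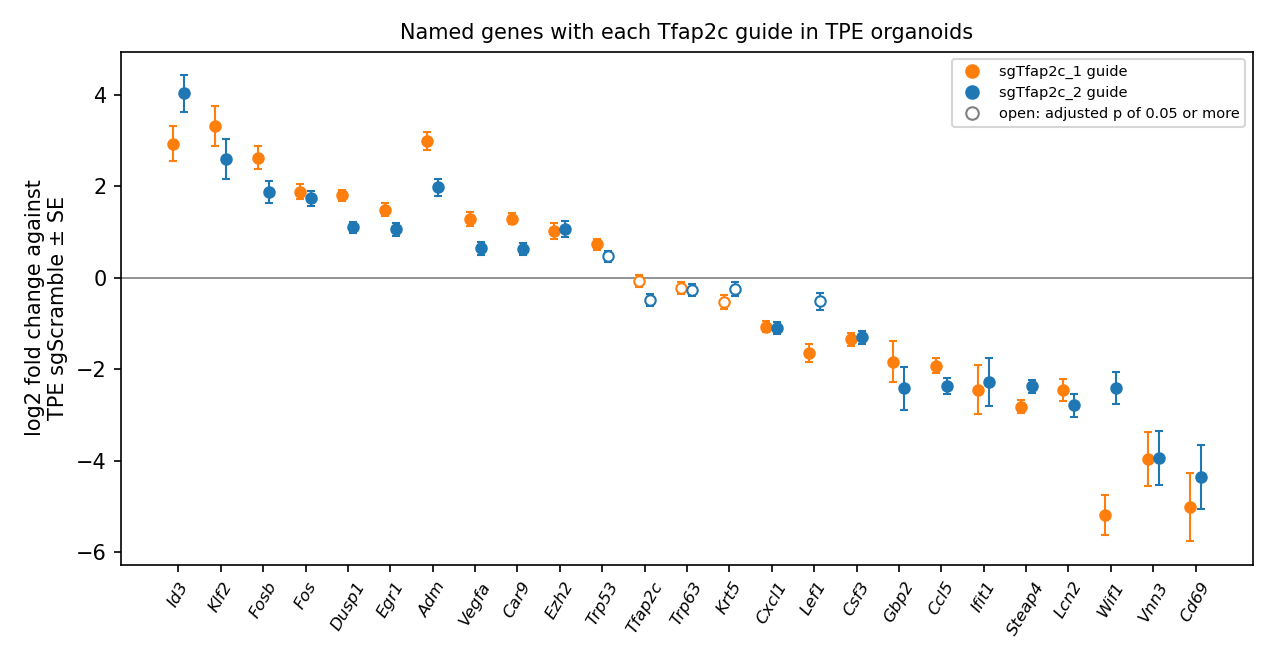
Log2 fold change ± SE against sgScramble of named genes in TPE organoids with sgTfap2c_1 (orange) and sgTfap2c_2 (blue), n = 3 libraries per group, with open symbols at an adjusted p of 0.05 or more. Immediate early and hypoxia genes lie above 0 and inflammatory and interferon genes below 0 with both guides, while Tfap2c itself did not pass with either.

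The Tfap2c guides were also compared with each other. sgTfap2c_1 called 988 genes higher and 717 lower, and sgTfap2c_2 582 and 418. Shared were 380 higher, 255 lower and 2 in opposite directions, the axon guidance gene Sema3a and E030002O03Rik. The fold changes had r = 0.656 across genes, against 0.486 in simulated unchanged groups (highest 0.531), and genes are not independent replicates. Their covariance was 0.25, against 0.049 in the simulations (highest 0.0553), and the same sign was found in 62.8% of genes, against 66.6%. Without sgTfap2c_2 replicate 1, 2 or 3 r was 0.825, 0.523 and 0.518, for which no simulation with a library left out was run. The direct comparison called 11 higher with sgTfap2c_1 and 7 lower (3198 at an unadjusted p under 0.05, and 496 and 503 by DESeq2). The count of sgTfap2c_1 was 767, 814, 534, 620, 584 and 599 without sgScramble replicate 1, 2 or 3 and sgTfap2c_1 replicate 1, 2 or 3. That of sgTfap2c_2 was 345, 342, 258, 5060 and 555 without sgScramble replicate 1, 2 or 3 and sgTfap2c_2 replicate 1 or 2. Between the guides edgeR called 0 without sgTfap2c_1 replicate 1, 2 or 3 (2035, 1673 and 1681 at an unadjusted p under 0.05, DESeq2 not run), and 2337, 5 and 1 without sgTfap2c_2 replicate 1, 2 or 3.

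The difference between the Ezh2 guide effects in tumor and normal organoids was tested directly. Of 13850 genes 312 differed, 253 with a higher effect in tumor and 59 with a lower one (2247 at an unadjusted p under 0.05, and 681 and 317 by DESeq2). In this joint fit both tables share 1 estimate of the spread, while TPE against TP alone called 0 of 13092 genes. The lowest r within a group was 0.858 in TP and 0.909 in TPE. It was 0.87, 0.99 and 0.847 in normal sgScramble, sgEzh2_1 and sgEzh2_2. These p-values thus rest in part on the spread of the normal libraries. Col4a1 was higher in TPE (3.59) and lower with the guides in normal organoids (-3.01, adjusted p = 0.0052, from -1.11 with sgEzh2_1 and -4.92 with sgEzh2_2), a difference of 6.60, and Tfap2c differed by 4.75. The count was 124, 110, 131, 133, 128, 184, 534, 687 and 201 without normal sgScramble replicate 1 or 2, sgEzh2_1 replicate 1, 2 or 3, sgEzh2_2 replicate 1 or 3, TP replicate 2 and TPE replicate 2.

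The overlap of calls between tables is tested here on DESeq2 calls, since edgeR in the main fit called 0 genes between TPE and TP. By edgeR with no filter on low counts, 12 genes changed in the same direction with the Ezh2 guides in normal and tumor organoids. In that setting 16 genes went with the Tfap2c guides against their direction in TPE. The other directions and a number by chance were not computed there, so these counts show neither agreement nor reversal. Of 13325 genes tested in both, 14 were higher with the Ezh2 guides in normal and in tumor organoids (5.81 by chance, Fisher's exact p = 0.00216) and 21 lower in both (4.04 by chance, Fisher's exact p = 5.96e-10). Examples are Serpinh1 and the kinase Dclk1, higher in both, and Sorbs2 and the water channel Aqp4, lower in both. In normal organoids these differences were larger with sgEzh2_2, with log2 fold changes for sgEzh2_1 and sgEzh2_2 of 0.63 and 2.61 for Serpinh1, 2.64 and 4.67 for Dclk1, 0.01 and -3.57 for Sorbs2, and -0.00 and -5.82 for Aqp4 (adjusted p of the difference between the guides 0.00152, 0.0275, 1e-04 and 0.00273). In opposite directions, 26 were lower in normal and higher in tumor organoids (8.91 by chance, Fisher's exact p = 1.04e-06), among them Col4a1 and Col4a2, and 8 were higher in normal and lower in tumor organoids (2.63 by chance, Fisher's exact p = 0.005), among them Gkn2 and Muc5ac, whose lower level in tumor organoids rests on TP replicate 1 alone. Genes shared in the same and in opposite directions thus both exceeded the number by chance, so the overlap does not show a common response. The number by chance and the Fisher p-values treat genes as independent and equally likely to be called, which was not tested. The fold changes had r = -0.0285 across 12529 genes.

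Whether the Tfap2c guides reversed the difference of TPE from TP was asked in the same way among 13542 genes, with the same limit on the p-values. Higher in TPE and lower with the Tfap2c guides were 40 genes (29.7 by chance, Fisher's exact p = 0.0331), such as Timp3 and Armcx2, and lower in TPE and higher with the guides were 10 (15.5 by chance, Fisher's exact p = 0.954), such as Crispld1 and Tnc. Changes in the same direction were 78 higher in both (39.7 by chance, Fisher's exact p = 3.23e-09), such as Bpifb4 and Sall3, and 37 lower in both (11.6 by chance, Fisher's exact p = 1.46e-10), such as Steap4 and Vnn1. As lists in the Tfap2c comparison, the 381 genes higher in TPE had a median log2 fold change of 0.19 (camera p = 0.033, p = 0.62 with an estimated correlation) and the 135 lower ones fell (median -0.18, p = 6.17e-07, and 0.000268 with an estimated correlation).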

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

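Chosen only after the results were seen were the tests of transcript length, of all explanations for the difference between the Ezh2 guides and of Xist, and the fits without the libraries that stand apart and with a length trend removed.

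The difference of the Ezh2 guide effects, TPE against TP in tumor organoids minus the mean of both guides in normal organoids, passed the edgeR test of the difference for 312 genes. Groups held at most 3 libraries, too few for a test of single distant libraries. Named genes with a higher effect in tumor organoids, as fitted log2 differences, were Armcx2 (3.16), Cda (5.08), Ckb (3.58), Col4a1 (6.60), Col4a2 (6.70), Col5a1 (8.69), Dlc1 (3.63), Eln (11.50), Foxd1 (7.53), H2-Ab1 (2.92), Hoxa2 (9.55), Hoxa3 (9.11), Hoxa5 (7.18), Krt8 (2.23), Nkd1 (6.91), Ror2 (11.34), Serpinh1 (7.67), Sh3tc1 (5.55), Tesc (6.59), Tfap2c (4.75) and Twist2 (5.91). Those with a lower effect in tumor organoids were B3galt2 (-8.69), Crispld1 (-7.11), Cxcl1 (-2.49), Cxcl3 (-4.74), Mndal (-4.12), Olfm4 (-11.83), Pde4b (-7.07), Ptgs2 (-3.49), Slitrk6 (-6.30), St8sia6 (-8.80), Steap4 (-4.00) and Tnfrsf11b (-5.28). Values of genes with 0 to 3 counts in a group, such as Eln, Hoxa2 and Ror2, depend on the prior count and are no bounds. The tumor and normal organoids also differ in genotype and origin, which the design does not separate.

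Libraries that stand apart from their groups were normal sgScramble replicate 3, normal sgEzh2_2 replicate 2 and TPE sgTfap2c_2 replicate 1. Short transcripts were higher in all 3, with Spearman rho of transcript length with the deviation from the group across genes of -0.689, -0.45 and -0.611, ribosomal and oxidative phosphorylation genes left out, so a length bias of the library or of its RNA is a candidate explanation. The other libraries of these tables ranged from -0.366 (normal sgEzh2_2 replicate 1) to 0.366 (replicate 3), so a smaller length trend was not limited to the 3. In the 3 libraries GC content given length had rho of -0.178, -0.492 and -0.288, between the bounds set for and against it, and stays open. Ribosomal protein genes were higher by medians of 1.5, 1.1 and 1.35, of which 0.294, 0.155 and 0.323 remained beyond the length trend, so a rise of their own also stays open. No biological explanation was tested, since the design puts these libraries in no group of their own.

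The Ezh2 guides differed in 982 genes. The distant libraries sgScramble replicate 3 and sgEzh2_2 replicate 2 as the whole cause are argued against by 1549 genes with the length trend removed and 2564 without them. The remaining replicates 1 and 3 of sgEzh2_2 also differed from each other (r = 0.943, against at least 0.99 within sgEzh2_1). An irregularity of the sgEzh2_2 group as a whole is not removed by these fits. 1 common response of unequal size, whichever guide lowered Ezh2 more, is argued against as the whole cause, since of the 57 genes past the test with sgEzh2_2 that also passed with sgEzh2_1, adjusted over the 677 genes of sgEzh2_2, 17 went in the opposite direction (40 in the same), such as Stc2 (1.79 ± 0.21 and -2.36 ± 0.21). The larger change with sgEzh2_2 in 77.5% of the 982 genes would count further against an unequal fall of Ezh2 mRNA only if sgEzh2_2 lowered it less, a difference that did not pass (-0.59 ± 0.24, adjusted p = 0.188), and such a response stays open as a part of the difference. A difference in the Ezh2 protein left, other targets of a guide and a different founding cell pool were not tested and may each contribute.

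Genes of chromosome Y had 0 counts in each of the 9 libraries with sgScramble or Tfap2c guides, against 34919 counts of Ddx3y, Eif2s3y, Kdm5d and Uty in the normal table and 15812 in the tumor table. Organoids of female origin that express Xist are argued against by its level, which was at most 0.519 CPM in the 9 libraries. Female organoids without Xist RNA were not tested. Chromosome Y left out of the counting of that table cannot be told apart from a loss of the chromosome in this line, because the other Y genes also had 0 counts, and those had only 216 and 171 counts in the other tables. The labels do not say whether this line is the one of the TPE libraries in the tumor table.

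Other splits of the libraries set the counts against chance. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 31 and 0 for sgEzh2_1, 677 and 3912 for sgEzh2_2 (2 of 10 as large), 982 and 0 between the Ezh2 guides, 1705 and 0 for sgTfap2c_1, 1000 and 0 for sgTfap2c_2, and 18 and 0 between the Tfap2c guides (1 of 10 each). For the mean of both guides 100 splits were drawn. For the Tfap2c guides the 1725 genes were above all other splits (1 of 100, highest other 1060). So were the 1101 genes with the guide libraries as 1 group (1 of 84, highest other 144). The splits treat libraries as independent. If the replicates of a group came from 1 culture, a chance difference between cultures would give the same result and is not excluded. For the Ezh2 guides the 193 genes were reached in 2 of 100 splits, but the highest other called 4427, which points to a structure of the samples, the split that puts sgScramble replicate 3 with sgEzh2_2 replicates 1 and 2. With the guide libraries as 1 group 0 genes were called by edgeR (860 at an unadjusted p under 0.05), so 84 of 84 splits were as large, with a highest other of 4750. Chance is not excluded for the number of lists, which was 12 with the Ezh2 guides (17 of 100, highest other 15) and 9 with the guides as 1 group (43 of 84, highest other 14). The same holds for the Tfap2c guides, with 6 lists (51 of 100, highest other 13) and 7 with the guides as 1 group (28 of 84, highest other 13). Taken singly, lists with the Ezh2 guides reached as small a p in these numbers of 100 splits, the real one included. They were parietal 1, Hox 2, neck 4, columnar 4, leukocyte 7, epithelial-mesenchymal 9 and basal squamous 10. Further up were developmental 17, unfolded protein 22, cell cycle 26, NRF2 31 and pit 36.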

How the results depend on the processing

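Chosen after seeing the data were the fits without the libraries that stand apart, with the length trend removed and with DESeq2 without single tumor libraries. Counts of genes are in the order sgEzh2_1, sgEzh2_2, mean of both, between the Ezh2 guides, sgTfap2c_1, sgTfap2c_2, mean of both and between the Tfap2c guides. RLE size factors kept each count within 1.5 times. DESeq2 gave 297, 1328, 579, 1651, 2676, 1867, 2580 and 999, 569 for TPE against TP and 998 for the difference of effects, with 35 and 50 genes in the overlaps. Its larger counts go with more false calls in the simulated data. With the replicate number as a block the counts that moved were 0 for sgEzh2_1 by edgeR (847 at an unadjusted p under 0.05, 297 by DESeq2 without a block), 298, 39, 465, 1052, 500, 1064 and 2. Deviations from the group means of libraries that share a replicate number correlated from -0.65 to 0.409 in the normal table and from -0.217 to 0.258 in the Tfap2c table. Pairing by number was thus not shown. It is not excluded, because deviations within a group sum to 0 and libraries that stand apart weigh on them. Without the libraries that stand apart the counts were 310, 1788, 675, 2564, 7397, 5060, 7051 and 2337, with 479 for the difference of effects, 10 lists with the Tfap2c guides and guide correlations of 0.191 and 0.824. With the length trend removed they were 85, 1316, 401, 1549, 2974, 2125, 3031 and 558, and 559 for the difference of effects. With only the libraries compared they were 245 for sgEzh2_2, 7358 for sgTfap2c_1, 97 for sgTfap2c_2 and 0 between the Tfap2c guides by edgeR (1901 at an unadjusted p under 0.05, 999 by DESeq2), and with the guides as 1 group 0 for the Ezh2 guides (860, 579 by DESeq2) and 1101 for the Tfap2c guides. Without a filter on low counts TPE against TP gave 326 genes, the difference of effects 486, the overlaps 12 and 16, and the guide correlations 0.353 and 0.548. An estimated correlation kept 2 lists with the Ezh2 guides, 0 between TPE and TP and 1 with the Tfap2c guides. DESeq2 gave 456, 1024, 275 and 254 for TPE against TP without TP replicate 1 or 2 and TPE replicate 1 or 2. Leaving out 1 library gave 0 to 10 genes for sgEzh2_1, 312 to 1461 for sgEzh2_2, 59 to 394 for their mean, 427 to 1885 between them and 0 to 101 for TPE against TP. It gave 534 to 814 for sgTfap2c_1, 258 to 5060 for sgTfap2c_2, 525 to 7051 for their mean, 0 to 2337 between them and 110 to 687 for the difference of effects. Lists numbered 7 to 15 with the Ezh2 guides, 12 to 21 between TPE and TP and 6 to 10 with the Tfap2c guides, overlaps held 0 to 4 and 0 to 11 genes, and guide correlations were 0.0565 to 0.253 and 0.518 to 0.825. A list counted as reversed where the direction of its test turned. A gene counted where its sign turned and it passed in the main edgeR fit or the alternative. Some medians changed sign without such a turn, as for epithelial-mesenchymal and developmental genes with the Ezh2 guides and leukocyte markers between TPE and TP. By this rule a pair of results reversed. The interferon list between TPE and TP had a median of 0.719 without TP replicate 2 (-1.42 to 0.719 over the libraries left out), and Cdkn2a with the Tfap2c guides was at -0.229 without sgTfap2c_2 replicate 1 (-0.229 to 0.288). Of 495 values of 55 genes named with the Ezh2 guides, 105 lost and 10 gained a call without 1 library and 0 reversed. For these changes the cause was not tested.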

Other observations

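The test of the cell cycle against the rise of Ezh2 was chosen only after that rise was seen. Between the Ezh2 guides in normal organoids, inflammatory chemokines and cytokines were higher with sgEzh2_2, with 7 of 26 past the edgeR test and 13 adjusted over the list alone (median -0.81, sgEzh2_1 over sgEzh2_2, adjusted p = 0.000692, but adjusted p = 0.33 with an estimated correlation). MHC class I genes were lower with sgEzh2_2, with 3 of 13 past the test and 4 adjusted over the list alone (median 0.85, adjusted p = 1.98e-05, but adjusted p = 0.291 with an estimated correlation). Neck cell markers were lower with sgEzh2_2, with 2 of 5 past the test and adjusted over the list alone (median 2.02, adjusted p = 9.13e-07, and 0.0297 with an estimated correlation).

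In TPE organoids with the Tfap2c guides, the shear-responsive factor Klf2 rose from 1.25 ± 0.288 to 10.1 ± 3.95 CPM (2.96 ± 0.41, adjusted p = 0.00331), and the muscle gene Mss51 from 0.286 ± 0.146 to 2.69 ± 0.491 (3.12, adjusted p = 0.00119). Timp3, an inhibitor of matrix metalloproteinases, fell from 17.4 ± 2.06 to 3.12 ± 1.11 CPM (-2.48 ± 0.23, adjusted p = 0.000756), and the interferon-induced GTPase gene Gbp10 was 9.74-fold lower (adjusted p = 0.0014). In normal organoids Sorbs2, an actin-binding adaptor, fell with sgEzh2_2, to 3.78 ± 0.57 CPM from 45 ± 11.8 with sgScramble (adjusted p = 0.000124), and was at 45.3 ± 1.96 with sgEzh2_1. Irx1, a homeobox factor, rose with sgEzh2_2, to 21.9 ± 4.32 CPM from 4.08 ± 0.813 (adjusted p = 0.000681), and was at 5.28 ± 0.319 with sgEzh2_1. The guides differed in both genes (adjusted p = 1e-04 and 0.00139).

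The higher Ezh2 mRNA with the Tfap2c guides might reflect more cycling cells, since Ezh2 is expressed in proliferating cells. The cell cycle list argued against this, with a median log2 fold change of -0.0745 and no call. What raised Ezh2 was not tested further.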
